A study of Homo sapiens with 2 samples.

How the data were processed

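The samples were 2 samples of HepG2 cells, 1 with the construct labelled Ad-NC and 1 with the construct labelled ad-LINC01126. Groups were taken from the transfection label of each sample. Per the labels' protocols, total RNA was extracted with TRIzol, 200 ng was dephosphorylated and ligated to a Cy3-labelled nucleotide, and the product was hybridised to Agilent miRNA arrays with 1 colour. Per the file headers, both arrays were of design 070156 and lay on the same slide in the same scan, so slide and scan do not separate the constructs. The submitters' processing notes name Agilent Feature Extraction 10.10, while the file headers give 11.5.1.1.

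The values used are spot intensity values deposited by the authors, per the file headers: the processed signal, which equals the background-subtracted signal and is not scaled between arrays. The deposited median spot and local background intensity, and Feature Extraction's total signal per miRNA, served as alternatives. Of 53144 spots on each array, 2164 control spots were left out, as were miRNA spots with an outlier flag (1273 on the Ad-NC array and 1657 on the ad-LINC01126 array). None of the miRNA spots was saturated.

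A probe was called detected on an array when more than 50% of its spots were well above background by Feature Extraction's flag, and a miRNA when at least 1 probe was. Of 5893 probes, 395 were detected on the Ad-NC array and 437 on the ad-LINC01126 array. Spots of a probe (median 10) were averaged, converted to log2, and the array's 75th percentile over the 382 probes detected on both arrays was subtracted. This percentile differed by 0.15 on the log2 scale between the arrays. The difference of a miRNA was the mean over its probes detected on both arrays, with several probes for 153 miRNAs and 1 probe for 69. 1 further miRNA was detected on both arrays through different probes and has no difference. Because the detection filter requires signal on both arrays, miRNAs found on 1 array alone were given only as a bound. The SE of a difference was built from the spread of spots around their probe's mean (median SD 0.15 and 0.16 log2 units), with a median of 0.06. It leaves out the disagreement between probes and all variation between cultures, extractions and arrays. The number of arrays, 1 per construct, limits the precision of every comparison.

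Named miRNAs follow a rule fixed before the data were examined. It takes the 12 largest differences in each direction among miRNAs whose probes all differ in 1 direction and whose difference exceeds 2 SE. A miRNA with 1 compared probe meets the condition on direction automatically. The rule adds the 2 members of each fixed list with the largest absolute differences, miR-122-5p, miR-21-5p, miR-192-5p and let-7a-5p, and the 5 largest bounds among miRNAs found on 1 array. There were 25 lists of miRNAs, covering liver, tumour, metabolic and stress themes, miRNA families, other cell types, fragments of other RNAs and the age of the catalogue entry. Lists with at least 3 compared members have a percentile among 10000 random lists drawn with matching over 5 bins of mean signal. These percentiles describe the 2 arrays and are no test of the constructs. Names were used as the files give them. A table of human genes on assembly GRCh38.p14 held 2497 of the 2549 names and was used only for which miRNAs neighbour each other, since the file headers name hg19, so no coordinates are given.

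The calculation was tested on a pair of arrays simulated from the Ad-NC array, with its 230 detected miRNAs, more than the 222 compared on the real arrays. All 20 miRNAs changed 2-fold and all 20 changed 1.5-fold, 10 raised and 10 lowered in each set, were recovered beyond 2 SE in the right direction. Their median log2 differences were 0.85 raised and -1.20 lowered at 2-fold, and 0.40 raised and -0.74 lowered at 1.5-fold. None of the 190 unchanged miRNAs passed 1.5-fold, and their median was -0.19. How many unchanged miRNAs passed 2 SE, the limit used for the changed ones, was not counted. The 75th percentile of the simulated arrays had moved by 0.18 beyond the shift put in, which lowers all differences alike. The 95% interval held the true value for 34.8% of the simulated differences as they stood, and for 91.7% after their common shift was removed. All probes of a simulated miRNA were given the same change, with noise between spots only. The simulation therefore does not cover disagreement between probes and gives no error rate for the real arrays.

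The 16 alternatives fixed before the data were examined covered scaling and normalization (75th percentile over all probes, median, none, quantile, loess with a span of 0.4), background correction, the summary per miRNA, the treatment of spots, the filter on dim probes, a 1.5-fold limit and a restriction to miRNAs numbered below 1000. Normexp, with an offset of 50, had been chosen for the mean spot signal before the data were examined and was run on the median spot signal instead, an input changed after the files were seen. Without the filter on dim probes, signals under 1 were set to 1. A further 3 alternatives were chosen after seeing the data: a brightness threshold common to both arrays, the same after scaling, and scaling on the labelling spike-ins. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.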

Results

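MicroRNA levels were measured in HepG2 cells, a human liver cancer line, 48 h after they received either of 2 constructs, named Ad-NC and ad-LINC01126 in the labels. The series was described as a test of how overexpression of LINC01126, a long intergenic non-coding RNA, changes miRNAs. Each construct was represented by 1 one-colour Agilent array hybridised with labelled product of 200 ng of total RNA. With 1 array per construct, no difference reported here has a replicate check. No p-value across replicates was computed, and the standard errors (SE) come from repeated spots within the arrays, so they cover measurement only. The array targets miRNAs, so the level of LINC01126 itself was not analysed here.

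Each array held 50980 spots for 2549 human miRNAs, and 1000 negative-control spots. The Ad-NC array detected 230 miRNAs (9.02%) and the ad-LINC01126 array 252 (9.89%). Of these, 223 were detected on both arrays, 7 on the Ad-NC array alone and 29 on the ad-LINC01126 array alone, while 2290 were detected on neither. Negative controls had a mean intensity of 3.94 (SD 3.77) on the Ad-NC array and 3.48 (SD 3.39) on the ad-LINC01126 array. The lowest detected probe signal was 20.5 on the Ad-NC array and 14.6 on the ad-LINC01126 array. No miRNA spot was saturated. Over the probes detected on both arrays, the ad-LINC01126 array was brighter, with a 75th percentile of 390 against 352. It was not brighter throughout: the median signal of each array's own detected probes was 74.8 there against 87.8.

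The question was which miRNAs differed after the LINC01126 construct. Of the 222 miRNAs with a probe detected on both arrays, 213 (95.9%) lay within 1.5-fold of each other. The oncogenic miR-21-5p had the largest higher value after ad-LINC01126, at 1.85-fold, and none of the 222 was 2-fold higher. With the brightest probe alone miR-21-5p differed by 0.36, below several others. Among these were miR-1260b (0.77), miR-6826-5p (0.69), miR-6780b-5p (0.61), miR-4465 (0.45) and miR-19a-3p (0.40). Its place as the largest therefore rests on its dimmer probe. Of the 222, 3 were at least 2-fold lower: miR-4668-5p, miR-548c-3p and miR-574-3p. A further 5 miRNAs, detected on the Ad-NC array alone, had bounds of at least 2-fold lower. These bounds rest on the lowest detected signal of the ad-LINC01126 array, 14.6, which was below that of the Ad-NC array, 20.5. At a 1.5-fold limit, 4 miRNAs were higher and 5 were lower. These counts depended on the processing: 4 miRNAs were 2-fold higher and 1 lower with the 75th percentile taken over all probes, 1 was 2-fold higher without scaling, and 5 were 2-fold higher and 7 lower with Feature Extraction's total signal per miRNA, which placed 30 miRNAs past 1.5-fold against 9 here. Both 2-fold counts were larger still without the filter on dim probes, which lets in undetected miRNAs. The log2 differences, ad-LINC01126 minus Ad-NC, had a median of -0.07 and an SD of 0.30, with 42 of the 222 higher and 92 lower beyond 2 SE. Across miRNAs, which are not independent replicates, the levels on the arrays correlated with Pearson's r of 0.990 and Spearman's rho of 0.978. The count of differences below 0 (142) and above 0 (80) depended on the scaling: taking the 75th percentile over all probes, detected or not, moved the median difference by 0.40, to 0.33, and without scaling the median was 0.07. Under the all-probe scaling, differences given below between -0.40 and 0 therefore have the opposite sign.

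**Figure D1:**
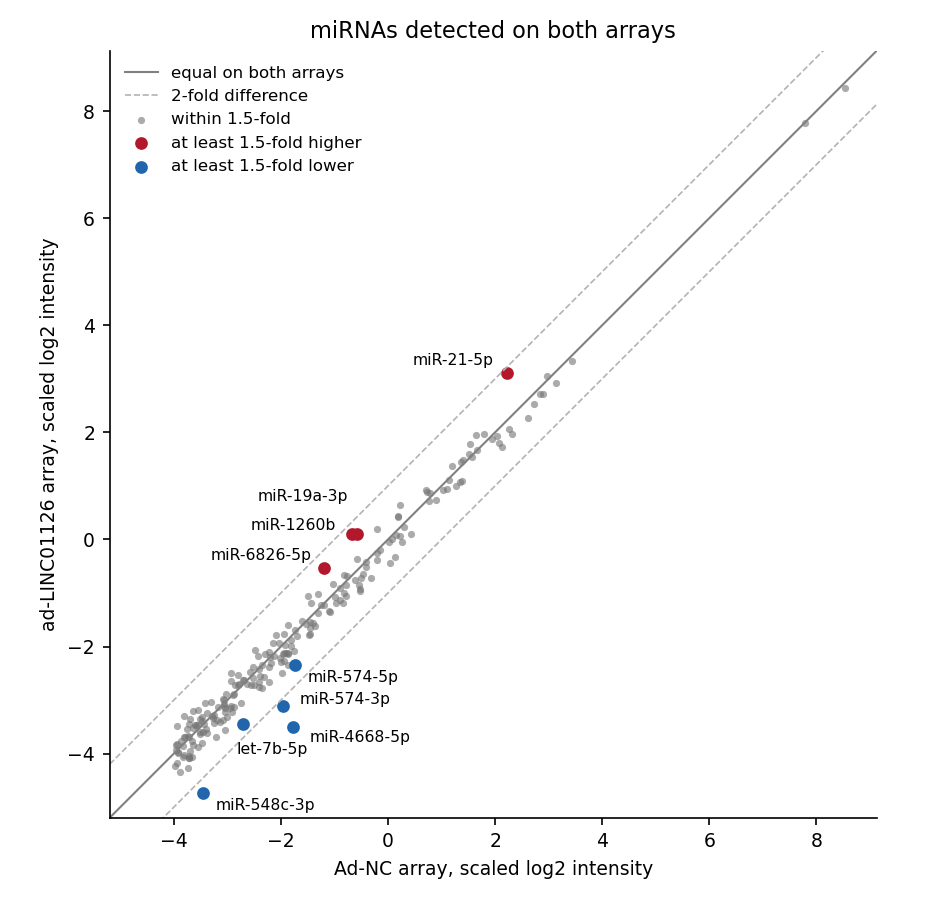
Each point is 1 of the 222 miRNAs detected on both arrays, plotted by its scaled log2 intensity on the Ad-NC array (x axis) and on the ad-LINC01126 array (y axis). The solid line marks equal levels and the dashed lines a 2-fold difference; 4 miRNAs lie at least 1.5-fold above the solid line and 5 at least 1.5-fold below it.

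Among the miRNAs that were higher after ad-LINC01126, miR-21-5p, which represses the tumour suppressor PDCD4, differed by 0.89 on the log2 scale (SE 0.20). Its probes were far apart: the brighter differed by 0.36 and the dimmer by 1.43. miR-19a-3p, a member of the miR-17-92 cluster, was 1.60-fold higher (log2 0.68, SE 0.14), with probes at 0.40 and 0.97. miR-1260b was 1.70-fold higher (log2 0.77, SE 0.08) on its single probe detected on both arrays, and both probes of miR-6826-5p placed it 1.59-fold higher (log2 0.67, SE 0.05). miR-429, a miR-200 family member that represses the transcription factors ZEB1 and ZEB2, was 1.43-fold higher (log2 0.52, SE 0.14). It was dim, at an intensity of 25.1 on the Ad-NC array. miR-215-5p, a p53-responsive miRNA that shares its seed with the liver-enriched miR-192-5p, was 1.34-fold higher (log2 0.43, SE 0.13), and miR-301b-3p, of the miR-130 seed family, was 1.35-fold higher (log2 0.43, SE 0.14). miR-1246, whose sequence is found in the U2 small nuclear RNA, was 1.37-fold higher (log2 0.45, SE 0.16), but was lower by a log2 difference of -0.95 when dim probes were not filtered. The remaining 4 of the 12 largest were miR-6780b-5p, miR-4465, miR-4665-3p and miR-6749-5p, with log2 differences of 0.44, 0.44, 0.36 and 0.35. Like miR-1260b, miR-301b-3p and miR-1246 rested on 1 compared probe each.

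Among the miRNAs that were lower after ad-LINC01126, both arms of the miR-574 precursor, which lies in an intron of FAM114A1, stood out in the same direction. miR-574-3p was lower by a log2 difference of -1.15 (SE 0.05; 2.22-fold), with probes at -1.07 and -1.24, and miR-574-5p by -0.61 (SE 0.06; 1.52-fold), with probes at -0.39 and -0.82. miR-4668-5p had the largest difference among these 222 miRNAs, -1.73 (SE 0.12; 3.33-fold), on 1 probe whose intensity was 103 on the Ad-NC array and 34.4 on the ad-LINC01126 array. miR-548c-3p differed by -1.29 (SE 0.43; 2.44-fold), also on 1 probe, and its intensity of 14.6 was the lowest detected on the ad-LINC01126 array. let-7b-5p, of the let-7 family that represses growth-promoting genes such as HMGA2 and RAS, differed by -0.74 (SE 0.07; 1.68-fold) on 1 probe. The 7 others of the 12 largest were miR-328-5p, miR-4507, miR-4306, miR-18b-5p, miR-4505, miR-1268b and miR-193a-3p, between -0.53 and -0.46. Of these, miR-328-5p, miR-18b-5p, miR-4505 and miR-193a-3p rested on 1 compared probe each. miR-4505 was higher, by 0.60, when dim probes were not filtered. With normexp background correction, which shrinks differences of dim probes, no miRNA was 2-fold lower.

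**Figure D2:**
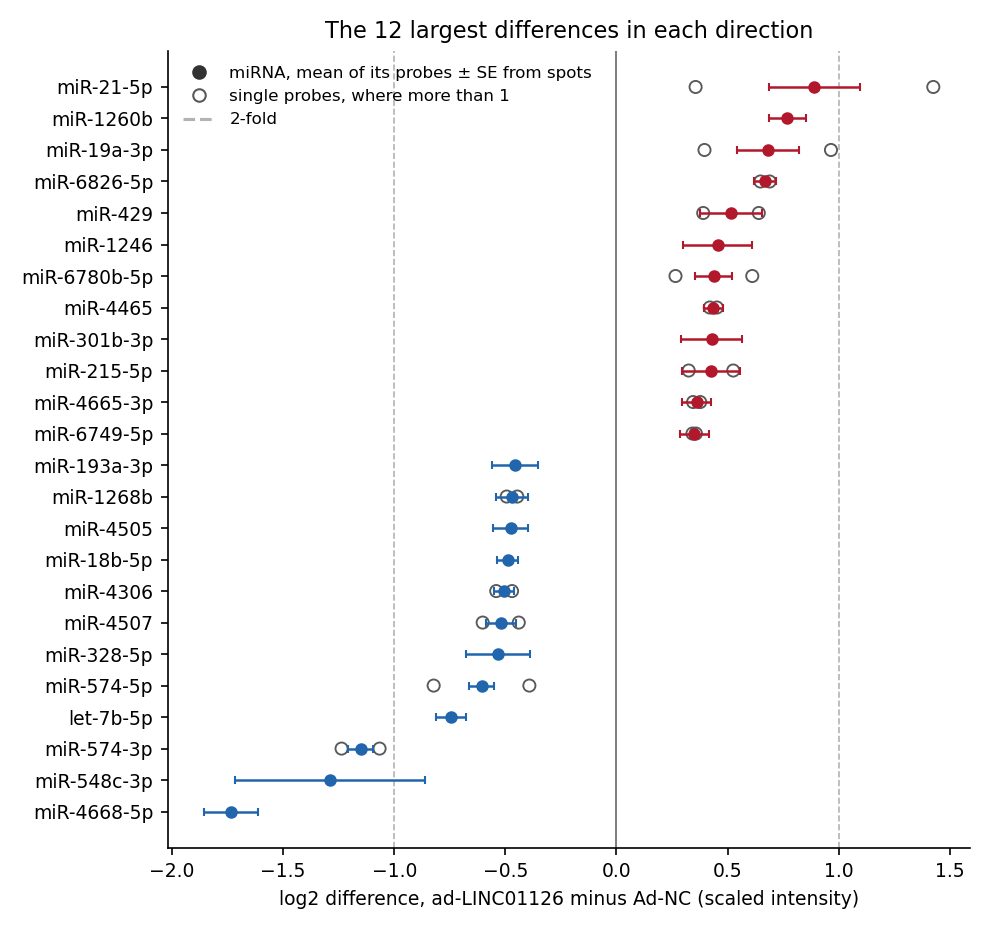
Log2 differences, ad-LINC01126 minus Ad-NC, for the 12 largest in each direction: filled points are the mean over a miRNA's probes, bars are 1 SE from spots within the arrays, and open circles are single probes where a miRNA had more than 1. miR-21-5p (0.89) and miR-4668-5p (-1.73) are the extremes, and the probes of miR-21-5p lie at 0.36 and 1.43.

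The scatter of the miRNA differences (SD 0.30) was set beside that of RNAs added to the samples, which were too few to fix a spread. The 4 spike-in controls with a pair of probes each differed by -0.36 to 0.39 (SD 0.32) after the same scaling, and 188 of the 222 miRNAs lay inside that range, 12 above it and 22 below it. Control sets of undescribed content with several probes lay closer together, between -0.20 and -0.03, except hur_5 at 0.71. Over all 10 control sets with several probes the SD was 0.33. Bright corner control spots, 361 on each array, differed by -1.20, against -1.07 and -1.24 for the probes of miR-574-3p. Probes of the same miRNA also diverged with brightness. In 100 of the 146 miRNAs with a pair of probes, the dimmer probe had the more positive difference, and the gap exceeded 2 SE in 36 of these. The gap exceeded 2 SE in the opposite direction in 5 miRNAs.

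**Figure D3:**
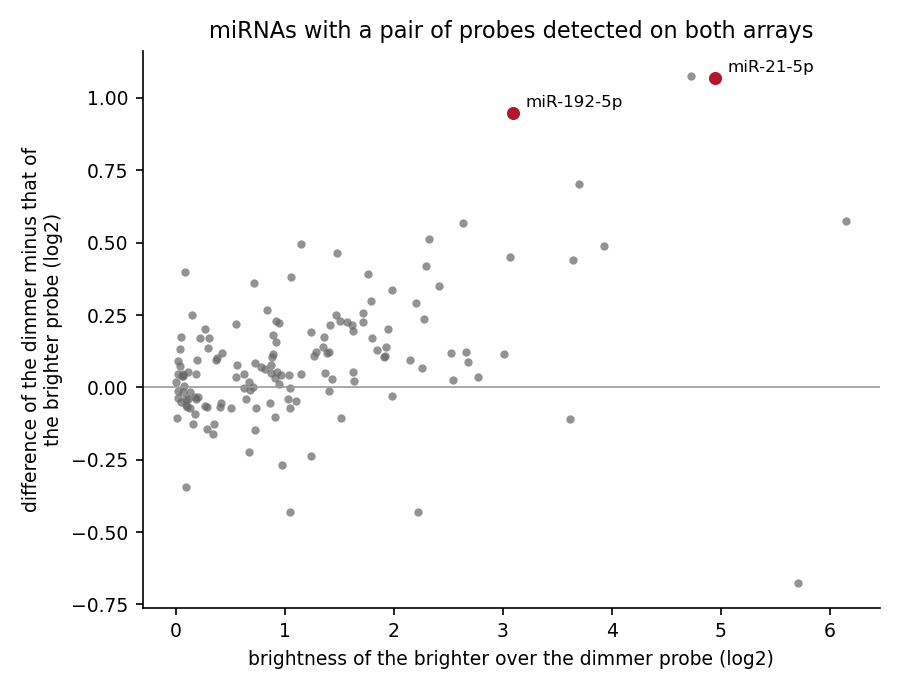
Each point is 1 of 146 miRNAs with a pair of probes: the x axis is how much brighter one probe was than the other (log2), and the y axis is the log2 difference (ad-LINC01126 minus Ad-NC) of the dimmer probe minus that of the brighter. 100 points lie above 0, and miR-21-5p and miR-192-5p, marked, are among the highest.

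Lists of miRNAs fixed before the data were examined are described by their median difference, by the distance of that median from the median of all 222 miRNAs, which a shift of the scale leaves as it is, and by its percentile among 10000 random lists of equal size and similar signal. The random lists were not matched on miRBase number. Apart from the fragments of other RNAs, the compared members of the theme and family lists were all numbered below 1000. The 126 compared miRNAs numbered below 1000 had a median of -0.15 themselves, with 15 higher and 60 lower beyond 2 SE. A list median near -0.15 is therefore not particular to its list. Taking the 75th percentile over all probes turned 14 of the 17 list medians below to the other sign. The miR-15-16 group, whose members repress BCL2 and cell-cycle genes, had a median difference of -0.33 over 4 members (percentile 1.03), which was 0.07 under that scaling. It lay at -0.26 relative to all miRNAs. In this group 3 members were lower beyond 2 SE, including miR-15a-5p (-0.46, SE 0.03) and miR-195-5p (-0.37, SE 0.09). The exception, miR-16-5p, named after its value was seen, differed by 0.07 (SE 0.08). miR-195-5p was among the middle members, which set the median. It rested on 1 dim probe, at intensities of 26.7 on the Ad-NC array and 22.9 on the ad-LINC01126 array. Without the filter on dim probes it differed by 0.32. The let-7 family had a median of -0.26 over 7 members (percentile 5.57), which was 0.14 under the all-probe scaling, and lay at -0.19 relative to all miRNAs. Of its members 5 were lower beyond 2 SE and none was higher beyond it; let-7e-5p differed by -0.43 (SE 0.05) and let-7a-5p by -0.28 (SE 0.06). The 1 let-7 member above 0 was let-7f-5p, named after its value was seen, at 0.20 (SE 0.11), with the brighter probe at -0.34 and the dimmer at 0.73. Using only the brightest probe of each miRNA raised no list median and lowered all but those of the miR-200 family and the immune and interferon list. The fall was therefore not particular to a family. It brought let-7 to -0.39 (percentile 0.32), the miR-15-16 group to -0.39 (0.89), liver-enriched miRNAs to -0.27 (5.86), miR-17-92 and paralogues to -0.17 (23.2), the miR-30 family to 0.09 (92.6) and all miRNAs numbered below 1000 to -0.18. The miR-200 family stayed at 0.20 (95.4).

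The miR-200 family, which maintains epithelial identity, had 3 members detected on both arrays, and all 3 were higher beyond 2 SE (median 0.20, percentile 95.5): miR-429, miR-200a-3p (0.20, SE 0.09) and miR-200b-3p (0.14, SE 0.05), the last named after its value was seen. The 2 other detected members, miR-141-3p and miR-200c-3p, also named after their values were seen, were found on the ad-LINC01126 array alone, at intensities of 21.7 and 17.8, too dim for a bound on the fold. The miR-30 family had a median of 0.18 over 3 members (percentile 96.2), of which 1, miR-30b-5p (0.26, SE 0.10), was higher beyond 2 SE and miR-30e-5p (0.18, SE 0.11) was not. These 2 family medians were above 0 under every scaling tried. Scaling on the labelling spike-ins moved the median of all differences by -0.01, and every other scaling raised it. Medians of 0.20 and 0.18 therefore had little room to turn, and their constant sign does not set these families apart. In the miR-17-92 cluster and its paralogues, 2 of 14 members were higher and 5 lower beyond 2 SE (median -0.08, percentile 45.0, above 0 without scaling, under quantile and loess normalization and under the all-probe scaling), with miR-19a-3p and miR-18b-5p at its ends. The miR-23-27-24 clusters had a median of -0.06 over 5 members (percentile 69.3, above 0 under the same 4 alternatives and when scaled on the median); miR-24-3p differed by -0.33 (SE 0.04) and miR-27a-3p by 0.10 (SE 0.04). The miR-181 family had 1 measured member, miR-181a-5p, at -0.18 (SE 0.08).

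Liver miRNAs were mixed. miR-122-5p, the predominant miRNA of adult liver, was detected on neither array, with probe intensities between 4.22 and 5.09, near the negative controls. The list of liver-enriched miRNAs had 1 member higher and 5 lower beyond 2 SE (median -0.16 over 7, percentile 22.8). The higher member was miR-192-5p, at 0.39 (SE 0.08), whose brighter probe differed by -0.09 and dimmer probe by 0.86, and the other arm of its precursor, miR-192-3p, differed by -0.39 (SE 0.19). Among miRNAs reported as raised in hepatocellular carcinoma, 3 were higher, among them both arms of the miR-21 precursor, and 7 lower beyond 2 SE (median -0.14 over 13, percentile 23.3). miR-21-5p was at the upper end and miR-106b-5p, hosted by the replication gene MCM7, at the lower (-0.34, SE 0.04). Among those reported as lowered in it, 2 were higher and 3 lower beyond 2 SE (median -0.12 over 12, percentile 32.5); miR-29b-1-5p differed by -0.38 (SE 0.24). Both carcinoma medians were above 0 without scaling and under the all-probe scaling, and that of the lowered list also under loess normalization, with a filter on all spots of a probe, and with Feature Extraction's total signal (0.18).

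**Figure D4:**
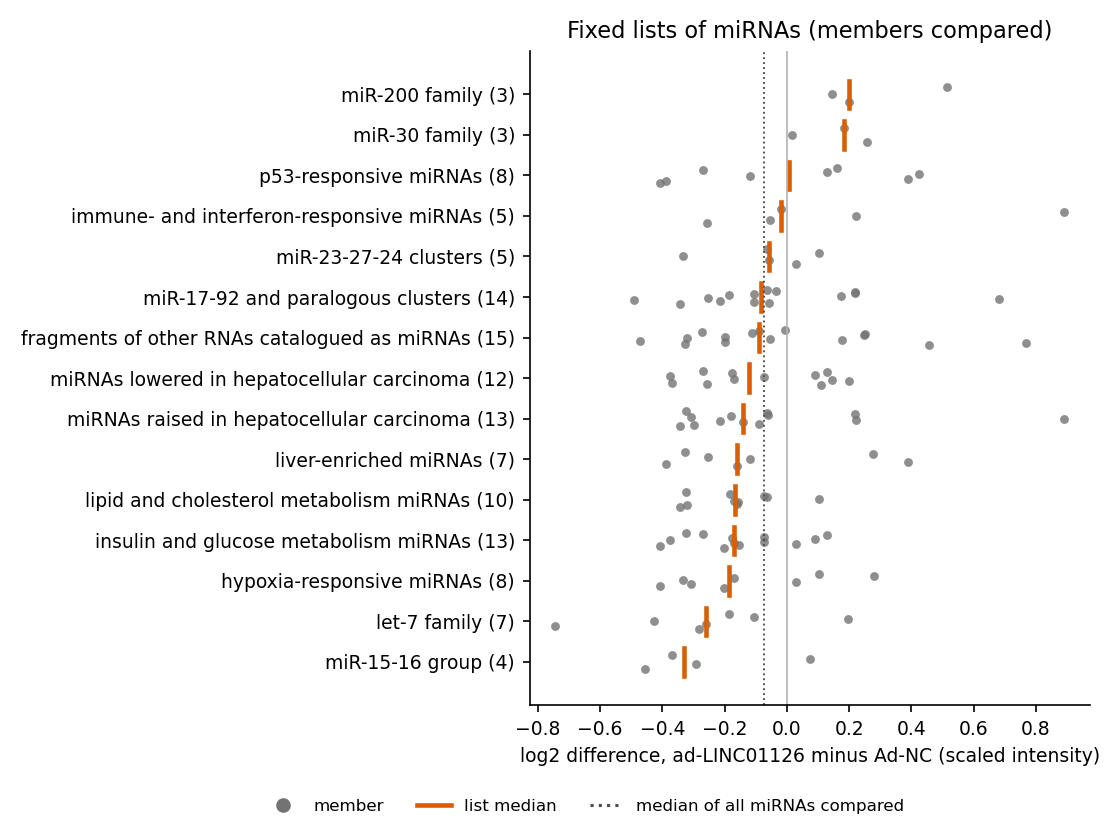
Log2 differences, ad-LINC01126 minus Ad-NC, of the members of 15 fixed lists (grey points, number of members in brackets), with each list's median (orange bar) and the median of all 222 miRNAs (dotted line, -0.07). List medians run from -0.33 for the miR-15-16 group to 0.20 for the miR-200 family, and 12 of these 15 turned sign under the all-probe scaling.

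Lists for metabolism and stress responses had medians between -0.19 and 0.01. The lipid and cholesterol list had 1 member higher and 7 lower beyond 2 SE (median -0.17 over 10, percentile 22.4); miR-128-3p, which represses the LDL receptor, differed by -0.32 (SE 0.06). The insulin and glucose list had none higher and 6 lower beyond 2 SE (median -0.17 over 13, percentile 9.02). miR-107, hosted by the pantothenate kinase gene PANK1, was its lowest member, at -0.41 (SE 0.03), and miR-96-5p differed by -0.32 (SE 0.04). The hypoxia list, which shares miR-107 with it, had 2 higher and 5 lower beyond 2 SE (median -0.19 over 8, percentile 12.1). These 3 medians and the liver-enriched one were above 0 under the all-probe scaling. They lay near -0.15, the median of miRNAs numbered below 1000, of which 60 of 126 were lower beyond 2 SE. The p53-responsive list had 2 higher, 3 lower and 3 within 2 SE (median 0.01 over 8, percentile 78.1, below 0 under 6 alternatives, at the lowest -0.09 with the brightest probe only). The immune and interferon list had 2 higher and none lower beyond 2 SE (median -0.02 over 5, percentile 66.7, above 0 under 8 alternatives, among them Feature Extraction's total signal with 0.25). The 2 higher members were the arms of 1 precursor, that of miR-21, led by miR-21-5p. In the same list miR-125a-5p differed by -0.26 (SE 0.14).

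Markers of other cell types were nearly absent. None of the 11 blood cell, 9 fibroblast and smooth muscle, 2 endothelial or 12 muscle miRNAs was detected on either array, nor was any of the 47 miRNAs of the chromosome 19 cluster. Of the 11 neural miRNAs 2 were detected, miR-128-3p, which the lipid list also holds, and miR-219a-5p (-0.11, SE 0.08). Of 92 miRNAs of the imprinted 14q32 cluster, miR-134-5p (0.09, SE 0.04) and miR-494-3p (0.01, SE 0.04) were detected. Catalogued miRNAs that are fragments of other RNAs, a sign of RNA quality, had 4 members higher and 8 lower beyond 2 SE (median -0.09 over 15, percentile 37.7, above 0 without scaling and under the all-probe scaling), from miR-1268b at -0.47 to miR-1260b at 0.77. miRNAs numbered 1000 and above had a median of -0.01 (96 miRNAs, percentile 99.7; above 0 under 5 of the 6 other scalings and with Feature Extraction's total signal), and those numbered below 1000 a median of -0.15 (126 miRNAs, percentile 0.12; above 0 under the all-probe scaling). Each miRNA is in 1 of these 2 lists, so the percentiles describe a single contrast.

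The miRNAs detected on the Ad-NC array alone were few but had the larger bounds, against a lower floor. A bound sets the signal of the brighter array against the lowest detected signal of the other, or the dim probe's own signal where that was higher. That lowest signal was 14.6 on the ad-LINC01126 array, from the single probe of miR-548c-3p, and 20.5 on the Ad-NC array (scaled log2 -4.74 and -4.11). The lower floor by itself enlarges the bounds of miRNAs found on the Ad-NC array alone. Bounds in the 2 directions are therefore not comparable in size. miR-197-3p was at least 3.36-fold lower after ad-LINC01126, miR-4455 at least 2.92-fold, miR-3151-3p at least 2.76-fold, miR-4701-5p at least 2.23-fold and miR-548ap-3p at least 2.14-fold. The other 2, miR-4701-3p (at least 1.88-fold) and miR-32-3p (at least 1.61-fold), were named after their values were seen. Intensities of all 7 on the Ad-NC array were between 21.2 and 44.3. Of the 29 detected on the ad-LINC01126 array alone, only miR-30c-5p, likewise named after its value was seen, had a bound above 1.5, at 1.52-fold higher. With 1 brightness threshold applied to both arrays, 12 miRNAs were found on each array alone.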

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

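All tests of the probe-pair pattern, and the stringency tests of the miR-574 pattern, were chosen after the result was seen. For the detection counts and a local defect, the predictions were fixed before the test results were seen. The common thresholds used for the detection counts were nonetheless chosen after seeing the data.

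The files class the hur_5 spots as controls without saying what they measure, so their meaning stays unknown; they had a higher signal on the ad-LINC01126 array. Their mean log2 difference after scaling was 0.71, with the 4 probes between 0.60 and 0.84, and their mean intensity was 55.8 on the Ad-NC array and 101 on the ad-LINC01126 array. The 361 bright corner control spots went the other way, from 124 to 59.5 intensity units, a log2 difference of -1.20 after scaling.

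The dimmer probe of a miRNA tended to read higher on the ad-LINC01126 array than its brighter probe, as with miR-21-5p (1.43 against 0.36) and miR-192-5p (0.86 against -0.09). The dimmer was the higher in 100 of 146 pairs. A change in the amount of each miRNA and nothing else would move proportionally responding probes alike, yet 41 of the 146 pairs lay more than 2 SE apart in either direction. A higher additive background is argued against by the negative controls, whose median was different by -0.454 intensity units on that array. Lower hybridisation or wash stringency on the ad-LINC01126 array stays open as a candidate explanation: in 8 of 10 sets of control probes the dimmest probe also had the more positive difference than the brightest, and the header's stringency ratio was 2.02 on that array against 2.48. The support is limited. Both of these probes were lower after scaling in 5 of the 8 sets, and 6 of the 10 sets are of undescribed content. The median gap was 0.08 (0.01 in hur_2). Both arrays also lay on the same slide, and a wash of the whole slide would not treat them differently.

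More miRNAs were detected on the ad-LINC01126 array alone (29) than on the Ad-NC array alone (7). Less noise, and so a lower detection threshold, may account for the excess: with 1 threshold of 24.0 intensity units on both arrays, 12 miRNAs were found on each array alone. Brighter signal among the probes detected on both arrays, on which the scaling rests, may add to it. The same threshold after scaling left 7 on the ad-LINC01126 array alone and 16 on the Ad-NC array alone. Over all probes the ad-LINC01126 array was not the brighter: the median difference was 0.33 with all-probe scaling against 0.07 without scaling, so its all-probe 75th percentile was the lower. An effect of the construct on the number of expressed miRNAs was not tested apart from these. The threshold of 24.0 lies above the lowest detected signal of each array, so it would also remove a real gain of dim miRNAs. The equal counts therefore cannot separate less noise from such a gain.

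Both arms of the miR-574 precursor were lower on the ad-LINC01126 array. A local defect is argued against by the spots, which are spread over the array: 38 of 38 were lower than the spot at the same place on the Ad-NC array. A technical difference such as stringency, which also moves control probes, cannot be told apart from a change in amount for either arm: the highest probes of miR-574-3p (-1.07) and miR-574-5p (-0.39) lay above the lowest control probe, the bright corner spots at -1.20. Among the other control probes, the lowest was at -0.40. A lower amount of the precursor after the LINC01126 construct remains a hypothesis that 1 array per construct cannot decide.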

How the results depend on the processing

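The alternatives with a threshold common to both arrays and with spike-in scaling were chosen after seeing the data. Of 664 values of the 45 named miRNAs under alternatives, 27 had the other sign, 11 of them under the all-probe scaling, and 15 of the 27 were of differences beyond 2 SE. Of the 24 largest differences, 22, all but miR-1246 and miR-4505, kept their sign in every alternative run. These were chosen for their size, and the lower ones all lay at -0.46 or below, so the all-probe shift of 0.40 could not turn them. Some margins were narrow: miR-6749-5p fell to 0.023 at the least and miR-193a-3p rose to -0.055 at the most. Of 254 values of the 17 list medians, 45 had the other sign, 14 of them under the all-probe scaling, and 8 of the 45 were of the 3 lists outside the middle 95% of random lists. The causes were not tested unless given. No paired analysis was possible because each construct has 1 array. Signal over background limits dim miRNAs, whose differences normexp shrinks. Leaving out the filter on dim probes enlarged some differences and shrank others: miR-1246 went from 0.45 to -0.95 and miR-219a-5p from -0.11 to 0.008.

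Scaling on the 75th percentile of all probes, most of them not detected, added 0.40 to every difference. The median became 0.33, with 4 miRNAs at least 2-fold higher and 1 lower. Differences beyond 2 SE turned sign for let-7a-5p (0.12), miR-106b-5p (0.059), miR-128-3p (0.084), miR-181a-5p (0.22), miR-192-3p (0.017), miR-195-5p (0.035), miR-24-3p (0.071) and miR-96-5p (0.080), as did those within 2 SE of miR-125a-5p (0.15), miR-219a-5p (0.29) and miR-29b-1-5p (0.027). Of the 14 list medians that turned, 3 were of those lists: the miR-15-16 group (0.073), miRNAs numbered below 1000 (0.25) and those numbered 1000 and above (0.39). The last median, close to 0, also turned to 0.065 with median scaling, 0.13 without scaling, 0.046 with quantile and 0.065 with loess normalization, and 0.068 with Feature Extraction's total signal. Without scaling, 1 miRNA was 2-fold higher.

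With no filter on dim probes, 14 miRNAs were 2-fold higher and 121 lower, the SD was 0.47, and sign turned for miR-1246 (-0.95), miR-192-3p (0.22), miR-195-5p (0.32), miR-30b-5p (-0.079) and miR-4505 (0.60). The medians of the miR-15-16 group and of miRNAs numbered 1000 and above were 0.0, because undetected members sit at the floor on both arrays. Normexp gave an SD of 0.17 and 0 miRNAs 2-fold lower. Feature Extraction's total signal gave 5 miRNAs 2-fold higher, 7 lower and 17 on the Ad-NC array alone; it also put miR-219a-5p at 0.56 and miR-29b-1-5p at 0.27. Of its 30 miRNAs past 1.5-fold, 6 were among the 9 of the main values. The brightest probe alone put miR-192-5p at -0.086, and of its 8 miRNAs past 1.5-fold, 6 were among those 9. Even-numbered spots put miR-27a-3p at -0.027. At 1.5-fold, 4 miRNAs were higher and 5 lower. Restricting to miRNAs numbered below 1000 left, with fewer miRNAs, 130 detected on the Ad-NC array, 147 on the ad-LINC01126 array and 3 on the Ad-NC array alone. With a common threshold, 12 miRNAs were found on the Ad-NC array alone and 12 on the other alone; after scaling, these were 16 and 7.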

Other observations

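The relations below were chosen after seeing the data, except the comparison of precursor arms, which was planned. Both arms were measured for 14 precursors, and in 10 of them both arms differed in the same direction. Both arms of miR-21 were higher after ad-LINC01126, the passenger arm miR-21-3p by 0.22 (SE 0.03), while the arms of miR-192 lay apart. Across precursors, which are not independent replicates, the differences of the arms had Pearson's r of 0.54 (two-sided permutation p = 0.0668, Benjamini-Hochberg adjusted p = 0.1002 over 3 relations) and Spearman's rho of 0.30 (permutation p = 0.301, adjusted p = 0.452). The relation rested on miR-574: over the other 13 precursors r was 0.32 (permutation p = 0.295). A permutation test of dimmer against brighter probes, across 146 miRNAs, gave r of 0.47 between the gap in brightness and the gap in difference (p = 1e-05, adjusted p = 3e-05, the smallest 100000 resamples can give before adjustment) and rho of 0.45.

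miRNAs encoded near each other are often made from the same transcript. Among 67 pairs within 10 kb, over 55 miRNAs, the median gap between log2 differences was 0.27, against 0.26 in shuffled pairs (one-sided permutation p = 0.581), and 34 pairs shared a direction. Neighbours were therefore not detectably closer than other pairs on these arrays.

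Near-identical miRNAs did not always have similar differences, although binding of a probe to related miRNAs was not scored here. miR-1260b differed by 0.77 (SE 0.08) and its close relative miR-1260a, named after its value was seen, by -0.33 (SE 0.08), with its brighter probe at -0.11 and its dimmer probe at -0.54. miR-19a-3p differed by 0.68 (SE 0.14) and miR-19b-3p, also named after its value was seen, by 0.17 (SE 0.14), with its brighter probe at -0.18 and its dimmer probe at 0.52.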
